A study of Mus musculus with 13 samples.

How the data were processed

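RNA sequencing libraries from sorted mouse CD4 T cells of the regulatory T cell (Treg) lineage were analysed, 13 in all, from Foxp3 reporter mice on a C57BL6/J background that were either wild type or lacked c-Rel, the NF-kB subunit encoded by Rel. Per the labels, the populations were pre-Tregs of the thymus (2 wild-type and 3 c-Rel knockout libraries), de novo Tregs of the thymus (2 and 2) and splenic Tregs (2 and 2). Cells were enriched magnetically for CD4 and sorted, and total RNA was isolated with a micro-scale column kit. Groups and replicate numbers follow the sample titles. No label states which libraries come from separate animals or cultures, so the p-values measure only the spread between libraries, which may be partly technical.

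The values used are the deposited raw counts of reads per gene, with no normalization by the authors. The submitters' processing notes name FastQC, MultiQC, STAR 2.5.2, Picard 2.9.0, featureCounts, Subread 1.5.2, limma and the genome build GRCm38. The annotation release and the strandedness of the count are not given in the sources used here. Each stage has a count table of its own. The pre-Treg table lists 47729 genes of all biotypes, with a deposited gene length in bases for each; the de novo and splenic tables list 22048 protein-coding genes. Stage therefore coincides with count table, and the splenic stage with tissue. All 13 per-sample columns were used and 0 were left out. Counts were checked to be whole numbers of 0 or more.

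Library totals, in counts, were 13656304 and 13698722 for wild-type pre-Tregs, 16133876, 29866696 and 16809052 for knockout pre-Tregs, 27455039 and 28235996 for wild-type and 25122095 and 26968168 for knockout de novo Tregs, and 33423147 and 34319459 for wild-type and 35114430 and 32291272 for knockout splenic Tregs. A floor of 3 counts corresponds to between 0.0853 and 0.223 CPM, the counts scaled by library size. The common biological coefficient of variation was 0.284 in pre-Tregs, 0.0939 in de novo Tregs and 0.131 in splenic Tregs, so the precision differs between stages.

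Genotype effects were estimated in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr with min.count 10 and min.total.count 15, and the quasi-likelihood F-test, separately for each stage. Over all stages, 1 genotype coefficient was fitted to the 13 libraries with stage as a covariate, on the genes present in all tables. A fit of the 6 group means to the same libraries gave the genotype by stage interaction, tested jointly and for each pair of stages, and the 2 stage comparisons in wild type. Adjusted p stands for the Benjamini-Hochberg adjusted p of the edgeR test unless another tool is named, and a gene is called, or said to rise, fall or change, at an adjusted p under 0.05. Values are log2 fold changes of knockout over wild type with the standard error (SE) of the fit, and group means in CPM with the standard deviation (SD). Where every library of a group had 0 counts the fold is a lower bound from the floor of 3 counts per library.

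Genes were named by a rule fixed before the data were examined. Rel comes first. For each genotype comparison, up to 10 called genes with the largest rise and up to 10 with the largest fall follow, given a mean of at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups; genes with only a model name, pseudogenes and antigen receptor segments were left out. Up to 4 called members of each gene list were added, by adjusted p, and a fixed set of NF-kB, Treg and survival genes was named whatever their p. Up to 10 genes were named for the interaction, and list members plus a fixed set of genes for the stage comparisons. Genes named outside the rule are marked as chosen after their values were seen.

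Gene lists fixed before the data were examined covered NF-kB subunits and regulators, the Treg signature, effector Treg genes, resting and lymphoid homing genes, early TCR response genes, IL-2 and STAT5 response genes, apoptosis and survival, proliferation, interferon response, glycolysis, ribosome biogenesis, helper T lineages, immature thymocytes, dissociation and heat shock, and sex-linked genes. Marker lists covered B and plasma cells, myeloid and dendritic cells, CD8 T and NK cells, erythroid cells and platelets, and thymic stroma. Cytosolic ribosomal proteins, oxidative phosphorylation and mitochondrially encoded genes were taken by name pattern. Each list with at least 5 tested members was tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01 on log-CPM with a prior count of 2, and adjusted over the lists of a comparison. For every list the number of called members is given as adjusted over all genes, and beside it as adjusted over the list alone. Camera was repeated with the correlation estimated for each list, and fry was run beside it.

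Overlap between stages was tested per direction with a two-sided Fisher exact test. The share of called genes within 10 Mb of Rel was compared with all other tested genes by the same test, since a knockout allele can carry linked variants.

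Alternatives fixed before the data were examined were size factors of the DESeq2 kind (RLE), no count filter, a minimum count of 50, DESeq2 1.42.0, limma-voom, a term for the replicate number of the titles, a term for the naming style of the pre-Treg sample descriptions, 1 fit sharing the spread over the stages, windows of 5 and 20 Mb around Rel, and leaving out each library in turn. Where leaving out 1 library leaves a group with 1, the lone library is assumed to vary like the others. Alternatives chosen after seeing the data were pre-Tregs with protein-coding genes only, the fit over all stages without the pre-Treg libraries, and the replicate number as a term across stages for the stage comparisons. Scaling by RLE moved no median log2 fold change by as much as 0.05, so no further scaling was tried.

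The pipeline was tested on simulated data with known changes. At a simulated 2-fold change it recovered 20.9% of changed genes in pre-Tregs, 85.1% in de novo Tregs, 67.2% in splenic Tregs, 85.1% over all stages and 5.97% for the interaction, and it recovered 43.3% in each of the 2 stage comparisons. At 4-fold the recovery was 68.2%, 93.9%, 83.3%, 84.8%, 59.1%, 71.2% and 68.2% in the same order. Among unchanged genes it called between 0 and 11 per comparison. Apart from the changes put in, the simulated genes had no difference between stages and the same spread in every library. The real spread differed between stages, so these values may not carry over to the comparisons that join stages.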

Results

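The data comprise 13 RNA sequencing libraries of sorted mouse Treg lineage cells at 3 stages, with and without c-Rel: pre-Tregs of the thymus (2 wild type, 3 knockout; 13656304 to 29866696 counts per library), de novo Tregs of the thymus (2 and 2; 25122095 to 28235996) and splenic Tregs (2 and 2; 32291272 to 35114430). After the count filter 14746, 11855 and 12264 genes were tested in the 3 stages, and 13058 over all stages. At the preset correlation camera made 34 list calls over the 4 genotype comparisons. These were 8 in pre-Tregs, 11 in de novo Tregs, 11 in splenic Tregs and 4 over all stages. With an estimated correlation camera made 0 calls, while fry also called 6 of the 11 lists in de novo Tregs.

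Rel, the gene targeted in the knockout, was read in every library. Wild-type pre-Tregs held 104 CPM (SD 2.64, n = 2) and knockout pre-Tregs 59.6 (SD 6.48, n = 3), a log2 fold change of −0.80 (SE 0.18, adjusted p = 0.552 by edgeR quasi-likelihood). De novo Tregs held 97.4 (SD 1.74) against 91.5 (SD 5.93), and splenic Tregs 50.2 (SD 6.45) against 43.3 (SD 1.82), with 2 libraries per group. The log2 fold changes there were −0.09 (SE 0.09, edgeR adjusted p = 0.665) and −0.21 (SE 0.13, adjusted p = 0.521), and −0.40 over all stages (SE 0.11, adjusted p = 0.16). Gene-level counts do not say which exons of Rel were read, so these levels do not check the genotype labels.

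**Figure D1:**
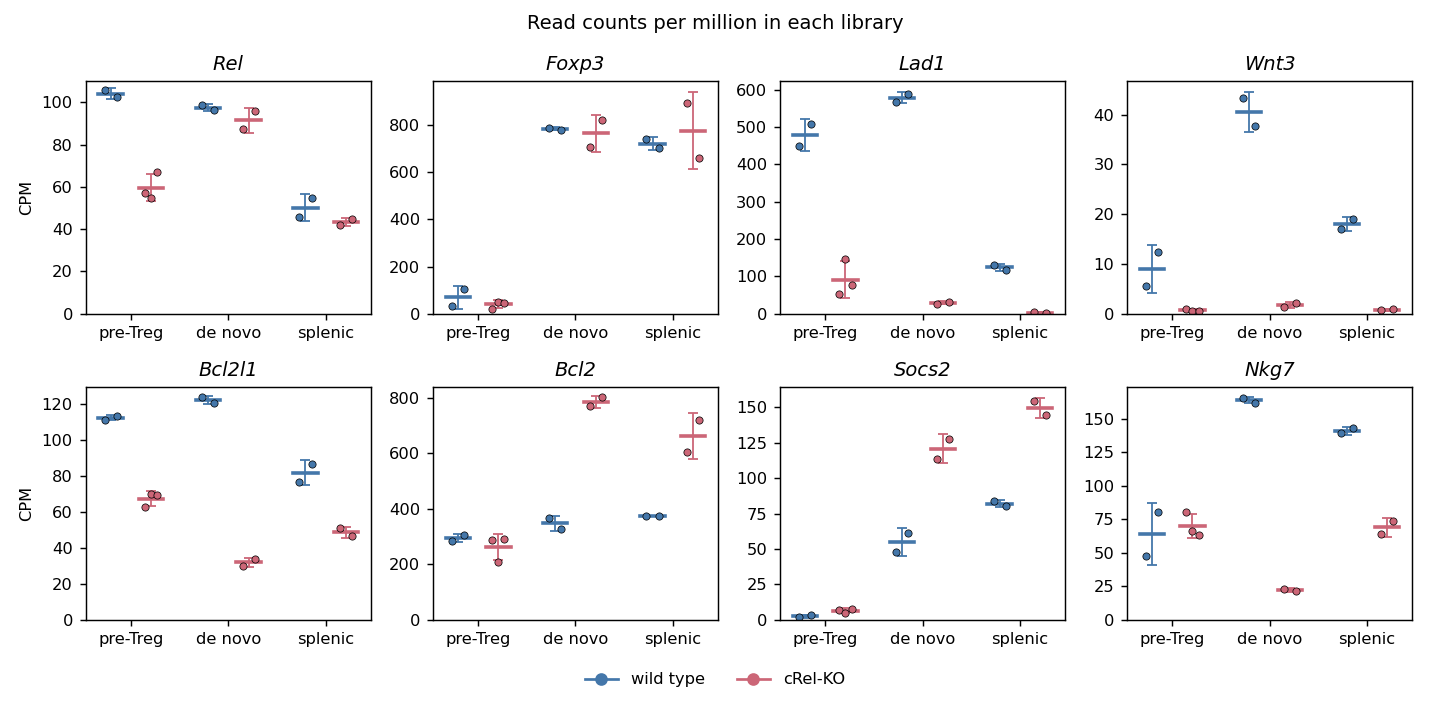
CPM per library (points) with mean and SD (bars) in wild-type and c-Rel knockout pre-Tregs, de novo Tregs and splenic Tregs for 8 genes. Lad1 averages 579 CPM in wild-type and 29.4 CPM in knockout de novo Tregs, while Foxp3 has overlapping levels at each stage.

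In pre-Tregs, Ikzf2, which encodes the Treg transcription factor Helios, averaged 519 CPM (SD 113, n = 2) in wild type and 161 CPM (SD 41.4, n = 3) in the knockout, a log2 fold change of −1.69 (SE 0.26) that did not pass the test (edgeR adjusted p = 0.307), though DESeq2 called it. Foxp3, the lineage-defining factor, stood at 68.6 (SD 50) against 39.5 CPM (SD 16.5; adjusted p = 0.724), and Bcl2l1, which encodes the survival protein Bcl-xL, at 112 (SD 1.39) against 67.3 CPM (SD 4.17; adjusted p = 0.565). Tnfaip3, a negative regulator of NF-kB, had a log2 fold change of 0.85 (SE 0.19, adjusted p = 0.552), and Il2ra, the high-affinity IL-2 receptor chain, 0.31 (SE 0.43, adjusted p = 0.828). Lad1, Wnt3 and St8sia6, chosen here after their values were seen, had log2 fold changes of −2.39 (SE 0.39), −3.72 (SE 0.49) and −2.14 (SE 0.22). Their adjusted p values were 0.307, 0.307 and 0.144 by edgeR, the last being the smallest of the stage.

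Of 14746 genes tested in pre-Tregs, 0 were called by edgeR and 0 by limma-voom, against 88 by DESeq2 (45 up, 43 down), and 969 had an unadjusted p under 0.05. Leaving out knockout replicate 2 gave 64 calls (33 up, 31 down), and leaving out any other library gave 0. A term for the naming style of the sample descriptions gave 67 calls (31 up, 36 down). Knockout replicate 2 is the only library of its style, so that term takes it out of the comparison. Proliferation genes had positive log2 fold changes for 29 of 30 members and glycolysis genes for 19 of 20. Camera put these lists at adjusted p = 3.99e-05 and 0.00311, and at 0.641 and 0.641 with an estimated correlation. No member of any list was called over all genes. Adjusted over the list alone, 1 NF-kB gene was higher and 2 lower. For the other lists, 3 early TCR response genes, 1 IL-2 and STAT5 response gene, 1 helper T lineage gene and 1 B cell marker were higher, and 2 genes each of the Treg signature, apoptosis and interferon lists were lower. Glycolysis did not pass camera without knockout replicate 2 (adjusted p = 0.0503). Myeloid and dendritic markers lay above 0 for 16 of 19 members (camera adjusted p = 9.15e-05; adjusted p = 0.641 with an estimated correlation), but at 0.172 without wild-type replicate 1. Camera also placed effector Treg genes higher (adjusted p = 0.0484, median log2 fold change 0.33) and ribosomal protein genes higher (0.000233). It placed the Treg signature (0.0204), mitochondrial genes (0.0032) and interferon response genes (0.00657) lower. All 5 had adjusted p = 0.641 with an estimated correlation, and each was lost in at least 1 fit that left out a library. Effector genes stood at 0.0927 without wild-type replicate 2, and ribosomal proteins at 0.281 without wild-type replicate 1. The Treg signature stood at 0.589 and mitochondrial genes at 0.702 without wild-type replicate 2, and interferon genes at 0.344 without wild-type replicate 1. Among the 5 sex-linked genes tested, 0 were called by edgeR, 0 by DESeq2 and 0 by limma-voom. At this spread a 2-fold change was recovered for 20.9% of simulated genes, so the count of 0 does not exclude moderate effects.

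In de novo Tregs lacking c-Rel, Lad1, which encodes a basement membrane anchoring protein, fell from 579 CPM (SD 15.2) to 29.4 CPM (SD 3.56, n = 2 per group; log2 fold change −4.30, SE 0.10, edgeR adjusted p = 1.55e-09). Wnt3, a secreted Wnt ligand, fell from 40.5 (SD 4.01) to 1.75 CPM (SD 0.554; −4.53, SE 0.20, adjusted p = 2.32e-07). Bcl2l1 fell from 122 (SD 2.35) to 31.9 CPM (SD 2.52; −1.94, SE 0.10, adjusted p = 6.05e-07), while Bcl2, another survival gene, rose from 348 (SD 27.6) to 787 CPM (SD 21.9; 1.18, SE 0.08, adjusted p = 5.37e-06). Socs2, a STAT5-induced feedback inhibitor, rose from 54.7 (SD 9.92) to 121 CPM (SD 10.1; 1.15, SE 0.12, adjusted p = 0.00019). Foxp3 was not called (−0.04, SE 0.08, adjusted p = 0.87). Since cells were sorted from Foxp3 reporter mice, its level in Tregs of either genotype may be set by the sort.

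Further large falls in de novo Tregs were in Klrg1, a receptor of differentiated Tregs (log2 fold change −3.59, SE 0.38), Ttc39c (−3.45, SE 0.26), Il1r2, the decoy IL-1 receptor (−3.11, SE 0.13), the chemokine gene Ccl5 (−3.06, SE 0.24), Bcl2a1d (−2.89, SE 0.16) and the granule gene Nkg7 (−2.88, SE 0.09). Their adjusted p values by edgeR ranged from 2.67e-08 for Nkg7 to 0.000202 for Klrg1. Bcl2a1d has close paralogs, and reads shared among them leave its own level uncertain. Among the genes named by the rule, the largest rises included Madcam1, the mucosal addressin (2.78, SE 0.38), the tyrosine kinase gene Fes (2.61, SE 0.21), Wnt10a (from 6.96 to 39.5 CPM), Cdhr3 (2.27, SE 0.26) and Ifitm3, an inhibitor of viral entry (1.89, SE 0.11). Gcg, the proglucagon gene, had 165 and 166 counts in the wild-type libraries and 0 in both knockout libraries, at least 51.0-fold lower. All of these kept their calls when any 1 library was left out. Of 11855 genes, 346 rose and 420 fell by edgeR, 71 and 171 of them at least 2-fold, and leaving out 1 library gave 527 to 761 calls.

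Effector Treg genes fell as a group in de novo knockout Tregs: of 26 tested, 15 fell, 0 rose and 11 were not called (21 fell when adjusted over the list alone), with a median log2 fold change of −0.87. Besides Klrg1, they include Fgl2, a secreted suppressor (−2.48, SE 0.20, adjusted p = 2.03e-05), the chemokine receptor gene Ccr6 (−1.36, SE 0.09, adjusted p = 5.54e-06) and the integrin gene Itgb1 (−0.76, SE 0.08, adjusted p = 0.000195). Camera gave adjusted p = 3.49e-11 for this list, and adjusted p = 0.483 with an estimated correlation. The number that fell stayed between 11 and 15 when 1 library was left out. In the fit sharing the spread over the stages 6 of 27 effector genes fell, 2 of 20 IL-2 and STAT5 response genes rose and 1 fell, and 1 of 30 Treg signature genes rose and 4 fell. IL-2 and STAT5 response genes moved mainly upward: 10 of 20 rose, among them Bcl2, Socs2, Osm (0.76, SE 0.11) and Il2ra (0.44, SE 0.07). Adjusted over the list alone, 11 rose and 3 fell. Over all genes 2 fell, including Gadd45b (−1.50, SE 0.15), and 1 fell without wild-type replicate 2. Camera gave adjusted p = 0.00353, and adjusted p = 0.524 with an estimated correlation. The Treg signature split, with 9 of 30 up and 11 down (10 and 13 over the list alone; camera adjusted p = 0.481). Gpr83 (0.96, SE 0.07), Ecm1 (1.13, SE 0.06) and Ctla4 (0.43, SE 0.07) rose, while Itgae (−2.18, SE 0.17) and Cd83 (−1.93, SE 0.08) fell.

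Ribosomal and mitochondrial transcripts were lower in de novo knockout Tregs. Of 79 cytosolic ribosomal protein genes 21 fell and 0 rose (37 fell over the list alone), for example Rps26 (−0.58, SE 0.10) and Rpl41 (−0.57, SE 0.08). The number was 8 without wild-type replicate 1, 6 without wild-type replicate 2 and 10 without knockout replicate 2. In the fit sharing the spread over the stages edgeR called 0 of the 79 ribosomal protein genes and 0 of the 11 mitochondrial genes. Of 11 mitochondrially encoded genes 7 fell over all genes and over the list alone, among them mt-Nd5 (−0.68, SE 0.08) and mt-Nd1 (−0.64, SE 0.07). Camera gave adjusted p = 3.27e-17 and 2.59e-08 for these lists, and adjusted p = 0.483 and 0.483 with an estimated correlation. The libraries themselves differ: mitochondrial genes took 0.429% and 0.46% of wild-type counts against 0.294% and 0.298% of knockout counts, and ribosomal protein genes 0.871% and 0.887% against 0.731% and 0.7%. Nuclear oxidative phosphorylation genes had 0 calls of 82 by edgeR, 0 by DESeq2 and 0 by limma-voom (0 over the list alone; camera adjusted p = 0.11). Glycolysis genes rose for 6 of 20, including Aldoc (1.24, SE 0.18) and Eno1 (0.51, SE 0.07), with 8 up and 2 down over the list alone. The rise held for 4 without wild-type replicate 1, 3 without wild-type replicate 2, and 4 without knockout replicate 1 or 2. Ribosome biogenesis genes fell for 2 of 22, including Npm1 (−0.49, SE 0.08), with 3 lower over the list alone, 1 called without wild-type replicate 1 and 3 without knockout replicate 1.

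The other lists had few calls in de novo Tregs. NF-kB subunits and regulators had 2 up and 3 down of 28 (3 and 3 over the list alone); Birc2, an inhibitor of apoptosis, fell (−0.47, SE 0.09, edgeR adjusted p = 0.00869), while Nfkb1, Nfkb2 and Rela were not called (adjusted p = 0.567, 0.64 and 0.864). Apoptosis and survival genes had 4 up and 4 down of 24 (4 and 5 over the list alone), with Bcl2 up and Bcl2l1, Bcl2a1d and Bcl2a1b down. Resting and lymphoid homing genes had 5 up and 1 down of 20 (7 and 3), among them Igfbp4 (1.36, SE 0.08) and Il6ra (0.51, SE 0.09). Early TCR response genes had 1 up (Spry1) and 3 down of 23 (1 and 7), including Tnfsf8 (−0.95, SE 0.09). Helper T lineage genes had 1 up and 3 down of 13 (1 and 5), with Ccl5 and Rora (−0.90, SE 0.09) lower. Interferon response genes had 2 up and 2 down of 28 (2 and 2), proliferation genes 2 up of 30 (2 over the list alone) and immature thymocyte genes 3 down of 22 (4 over the list alone), including Tox2 (−1.88, SE 0.26). Each of the 4 libraries, when left out, moved at least 1 of these small counts by more than 1.5-fold.

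Markers of other cells were measured in the same libraries. CD8 T and NK cell markers had 3 lower of 10 (1 higher and 4 lower over the list alone), including Nkg7 and Ctsw (−0.61, SE 0.08). Thymic stroma markers had 2 higher of 7 (2 over the list alone), Epcam (0.80, SE 0.13) and Pecam1 (0.40, SE 0.07). B and plasma cell markers had 1 up and 1 down of 8 (1 and 3 over the list alone), with 0 called without wild-type replicate 1 and 0 without knockout replicate 2. Erythroid and platelet markers had 2 lower of 5 (3 over the list alone). Wild-type replicate 1 had a summed level of 106.9 CPM against 4.72, 2.55 and 3.45 in the other de novo libraries. Without it 1 of 5 was called lower, and 5 of 7, 4 of 8 and 4 of 7 without wild-type replicate 2 and knockout replicates 1 and 2. Myeloid and dendritic markers had 0 called of 15 by edgeR, 0 by limma-voom and 1 by DESeq2, with 14 below 0 and 3 lower over the list alone. With the replicate number as a block 3 were called lower. Camera placed them lower (adjusted p = 0.00875, and adjusted p = 0.675 with an estimated correlation), but at 0.715 without wild-type replicate 1 and 0.101 without knockout replicate 2. Dissociation and heat shock genes had 0 called of 10 by edgeR, 0 by limma-voom and 1 by DESeq2, with 1 lower over the list alone, and 5 fell without knockout replicate 2.

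**Figure D2:**
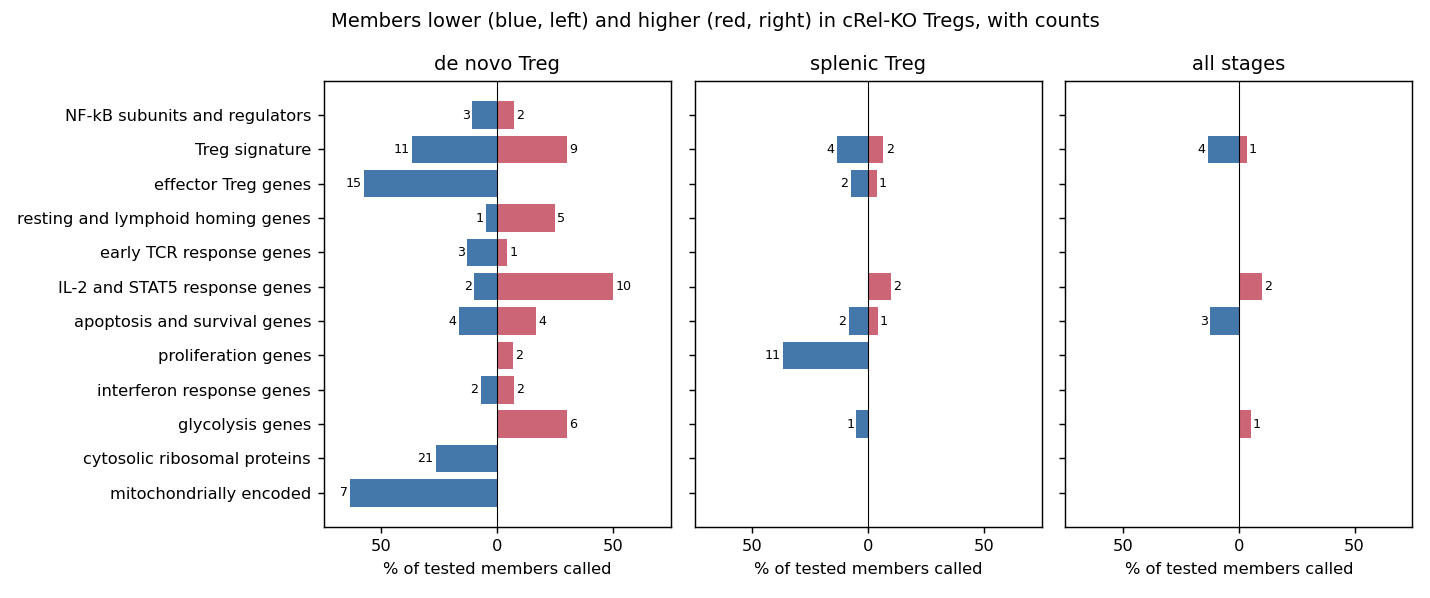
Percent of tested members called higher or lower in c-Rel knockout cells for 12 gene lists, in de novo Tregs, in splenic Tregs and over all stages. Of 26 effector Treg genes 15 are lower in de novo Tregs, and of 30 proliferation genes 11 are lower in splenic Tregs.

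In splenic Tregs lacking c-Rel, Lad1 fell from 124 CPM (SD 9.59) to 2.91 CPM (SD 1.92, n = 2 per group; log2 fold change −5.39, SE 0.35, edgeR adjusted p = 0.00175) and Wnt3 from 18.1 (SD 1.39) to 0.809 CPM (SD 0.218; −4.48, SE 0.24, adjusted p = 0.000885). Ifitm3 rose from 12.03 (SD 1.35) to 44.5 CPM (SD 3.88; 1.89, SE 0.15, adjusted p = 0.00316), Bcl2 from 374 (SD 0.373) to 663 CPM (SD 82.8; 0.83, SE 0.11, adjusted p = 0.0196) and Socs2 from 82.1 (SD 2.56) to 149.7 CPM (SD 6.87; 0.87, SE 0.10, adjusted p = 0.0169). Other falls were in Colq (−2.46, SE 0.14), the amino acid transporter gene Slc7a10 (−2.46, SE 0.22), the chemokine receptor gene Ccr9 (−1.82, SE 0.23) and Ncf1, an NADPH oxidase subunit (−1.76, SE 0.20). Other rises were in Obp2a (3.16, SE 0.36), Igfbp7 (2.26, SE 0.18), Wnt10a (2.16, SE 0.21) and the checkpoint receptor gene Ctla4 (0.86, SE 0.11, adjusted p = 0.0196). Bcl2l1 fell (−0.75, SE 0.12, adjusted p = 0.035) but was not called without wild-type replicate 2 (adjusted p = 0.147). Foxp3 (0.11, SE 0.14, adjusted p = 0.795) and Ikzf2 (0.17, SE 0.11, adjusted p = 0.577) were not called.

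Of 12264 genes tested in splenic Tregs 75 rose and 93 fell by edgeR, 44 and 66 of them at least 2-fold. Leaving out wild-type replicate 1 gave 278 calls, knockout replicate 1 gave 2508 and knockout replicate 2 gave 1548. In those fits the lone library is assumed to vary like the others. Proliferation genes were lower as a group: of 30 tested all 30 had negative log2 fold changes (median −1.19), and 11 fell over all genes. Adjusted over the list alone 30 fell. Examples are Cdc20, from 67.4 (SD 0.151) to 29.5 CPM (SD 5.89; −1.19, SE 0.15, adjusted p = 0.0196), the cyclin gene Ccna2 (−1.69, SE 0.28), Plk1 (−1.36, SE 0.20) and Aurka (−1.31, SE 0.19). Their summed level was 2900.5 and 3129.6 CPM in wild type against 2042.2 and 1336.8 CPM in the knockout. Camera gave adjusted p = 1.27e-17, and adjusted p = 0.798 with an estimated correlation. The number that fell was 22 and 21 without wild-type replicate 1 and 2, and 30 and 28 without knockout replicate 1 and 2.

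The remaining lists had few calls in splenic Tregs with all 4 libraries, and the low counts depend on both knockout libraries. With all libraries 0 ribosomal protein and 0 oxidative phosphorylation genes were called by edgeR, 0 by DESeq2 and 0 by limma-voom. Yet 60 of 79 and 71 of 82 lay below 0, and camera at the preset correlation placed both lists lower. Their median log2 fold changes were −0.10 and −0.11, and 0.012 and −0.0039 without knockout replicate 1. In the fit without knockout replicate 2 the medians were −0.20 and −0.23. In that fit 7 NF-kB genes, 6 interferon response genes, 8 IL-2 and STAT5 response genes and 6 B and plasma cell markers rose, and 12 Treg signature genes rose and 9 fell. Without knockout replicate 1, 9 NF-kB and 9 interferon response genes rose, 8 Treg signature genes rose and 8 fell, and 9 ribosome biogenesis, 7 glycolysis, 5 CD8 T and NK and 4 heat shock genes fell. Effector Treg genes had 1 up and 2 down of 27 (3 and 6 over the list alone; camera adjusted p = 0.268). They had 5 up and 10 down without knockout replicate 1, 4 up and 10 down without knockout replicate 2, 1 up and 1 down without wild-type replicate 1, and 1 up without wild-type replicate 2. DESeq2 gave 3 up and 5 down, and limma-voom 1 up and 1 down. NF-kB subunits and regulators had 0 calls of 28 by edgeR over all genes and 5 up over the list alone, with 23 positive log2 fold changes. Camera gave adjusted p = 0.00461 for them, adjusted p = 0.798 with an estimated correlation, and 0.0651 without wild-type replicate 2. Heat shock genes Hspa1a (2.21, SE 0.39, adjusted p = 0.0442) and Hspa1b (2.35, SE 0.33, adjusted p = 0.029), near-identical paralogs that share reads, were the 2 called of the 11 dissociation and heat shock genes (4 higher and 2 lower over the list alone). In markers, Nkg7 fell (−1.03, SE 0.11), the 1 called of 12 CD8 T and NK genes (3 over the list alone). Of these 12 genes 11 lay below 0, with a median log2 fold change of −0.67. B and plasma cell markers lay above 0 for 10 of 11, with 114.5 summed CPM in knockout replicate 1 against 44.6 to 65.1 CPM in the other 3 libraries. Myeloid and dendritic markers lay below 0 for 16 of 19, with 0 called by edgeR, 0 by limma-voom and 2 by DESeq2. Camera gave adjusted p = 0.00279 for them, and adjusted p = 0.863 with an estimated correlation. The number called lower was 5 and 3 without wild-type replicate 1 and 2, and 14 and 4 without knockout replicate 1 and 2. Of the 4 sex-linked genes tested in de novo and in splenic Tregs edgeR, DESeq2 and limma-voom called 0. Leaving out 1 library gave 2 higher in one de novo fit, 3 lower in another and 4 lower in one splenic fit, so these counts do not show that the groups match.

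De novo and splenic Tregs shared calls well above the number expected by chance. Among 11639 genes tested in both, 36 rose in both (2.09 expected; two-sided Fisher exact p = 1.1e-36) and 34 fell in both (3.26 expected; exact p = 3.65e-26). In opposite directions 6 were called. The exact test treats genes as independent, which they are not, so its p-values serve as description only. Wnt3, Lad1, Bcl2a1d, Nkg7 and Tox2 are among the shared falls, and Wnt10a, Ifitm3, Bcl2, Socs2 and Ctla4 among the shared rises. Of the de novo calls 84.8% had the same sign in the spleen, as had 65.2% of the splenic calls in de novo Tregs (107 of 164), and the Pearson correlation across genes was 0.363. Of the 70 shared genes 63 were tested in pre-Tregs, where 44 had the same sign and 20 of these an unadjusted edgeR p under 0.05. Over all calls tested in both stages, 424 of 727 de novo calls (58.3%) and 70 of 144 splenic calls (48.6%) had the same sign in pre-Tregs. Pearson correlations with pre-Tregs across genes were 0.0751 for de novo and −0.0784 for splenic Tregs.

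**Figure D3:**
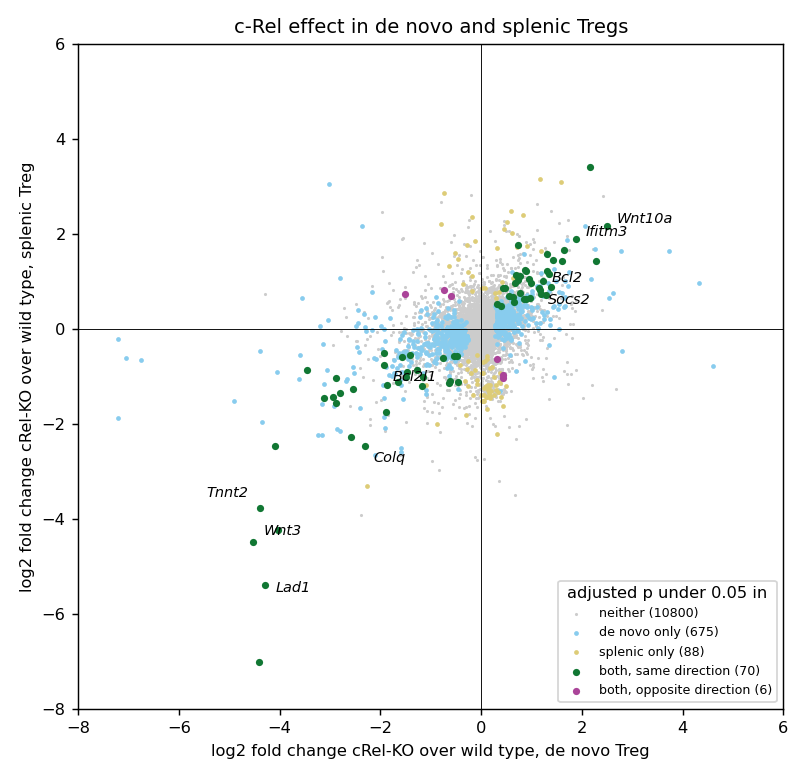
Log2 fold change of c-Rel knockout over wild type in de novo Tregs (horizontal) and splenic Tregs (vertical) for 11639 genes tested in both, each gene 1 point coloured by where it was called. Called genes comprise 675 in de novo Tregs only, 88 in splenic Tregs only, 70 in both with the same sign and 6 with opposite signs; 4 genes lie outside the axes.

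Over all stages (6 wild-type and 7 knockout libraries), the largest falls among the named genes that kept their calls without any 1 library were in Wnt3 (−4.27, SE 0.23, edgeR adjusted p = 3.64e-07), Lad1 (−3.93, SE 0.44, adjusted p = 0.000576), the proteoglycan gene Sdc4 (−2.11, SE 0.20, adjusted p = 0.000167) and Colq (−2.01, SE 0.18, adjusted p = 0.000156). Bcl2l1 (−1.12, SE 0.16, adjusted p = 0.00413), the death receptor gene Fas (−0.63, SE 0.07) and Ikzf4, which encodes the Treg factor Eos (−0.65, SE 0.10), also fell. Ifitm3 (1.53, SE 0.17), Cd74, the invariant chain gene (1.14, SE 0.11), Socs2 (1.09, SE 0.14) and Socs3 (0.54, SE 0.08) rose. Summed B and plasma cell markers were also higher in the knockout at each stage. Their means were 31.7 against 18.8 CPM in pre-Tregs, where the libraries overlapped. They were 40.8 against 36.3 CPM in de novo and 89.8 against 50.9 CPM in splenic Tregs. Whether such cells add to the rise of Cd74 was not tested. Foxp3 (adjusted p = 0.729), Il2ra (0.605), Ikzf2 (0.378) and Bcl2 (0.247) were not called. Of 13058 genes 41 rose and 70 fell, 20 and 33 at least 2-fold. The count was 69 without pre-Treg wild-type replicate 2, and 174 and 217 without pre-Treg knockout replicates 1 and 2. It was 44, 57, 47 and 51 without de novo wild-type replicates 1 and 2 and knockout replicates 1 and 2. It was 62, 63 and 71 without splenic wild-type replicates 1 and 2 and knockout replicate 2. IL-2 and STAT5 response genes had 2 up of 20 (4 up and 2 down over the list alone; camera adjusted p = 0.0188, and adjusted p = 0.824 with an estimated correlation), and effector Treg genes 0 of 27 by edgeR (4 down over the list alone). Camera placed effector genes (adjusted p = 0.0283), mitochondrial genes (0.0188) and proliferation genes (0.0484) lower, with adjusted p = 0.946, 0.824 and 0.946 with an estimated correlation. Effector genes stood at 0.116, 0.219, 0.0829 and 0.254 without de novo wild-type replicates 1 and 2 and knockout replicates 1 and 2, and mitochondrial genes at 0.0596 without de novo wild-type replicate 2. Proliferation genes stood at 0.0509 without de novo wild-type replicate 1, and at 0.417, 0.551, 0.122 and 1.00 without the splenic libraries in the same order.

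The genotype effect differed between stages for 21 genes by the joint interaction test (edgeR, 1374 at unadjusted p under 0.05). Nkg7 had log2 fold changes of 0.13 (SE 0.25), −2.88 (SE 0.09) and −1.03 (SE 0.11) in pre-Tregs, de novo Tregs and splenic Tregs (interaction adjusted p = 0.00596). Itgae, the integrin chain CD103, had −0.21, −2.18 and 0.79 (adjusted p = 0.0111), and is the 1 gene for which splenic and de novo effects differed directly (adjusted p = 0.00913). Fgl2 had 1.00, −2.48 and 0.06 (adjusted p = 0.0136) and Tigit, an inhibitory receptor, 0.97, −2.48 and −0.39 (adjusted p = 0.0152). De novo and pre-Treg effects differed for 11 genes, and splenic and pre-Treg effects for 28. The fit of the group means had a common biological coefficient of variation of 0.189, against 0.284 in pre-Tregs alone. Contrasts with pre-Tregs may thus rest on too small a spread. The count of 21 became 10, 6, 214, 296 and 9 without pre-Treg wild-type replicates 1 and 2 and knockout replicates 1 to 3. It became 10, 3, 4 and 0 without de novo wild-type replicates 1 and 2 and knockout replicates 1 and 2, and 10, 8, 90 and 7 without the splenic libraries in the same order. Without de novo knockout replicate 2 no gene kept its call; the adjusted p of Nkg7 and of Rcn1 was then 0.0879.

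**Figure D4:**
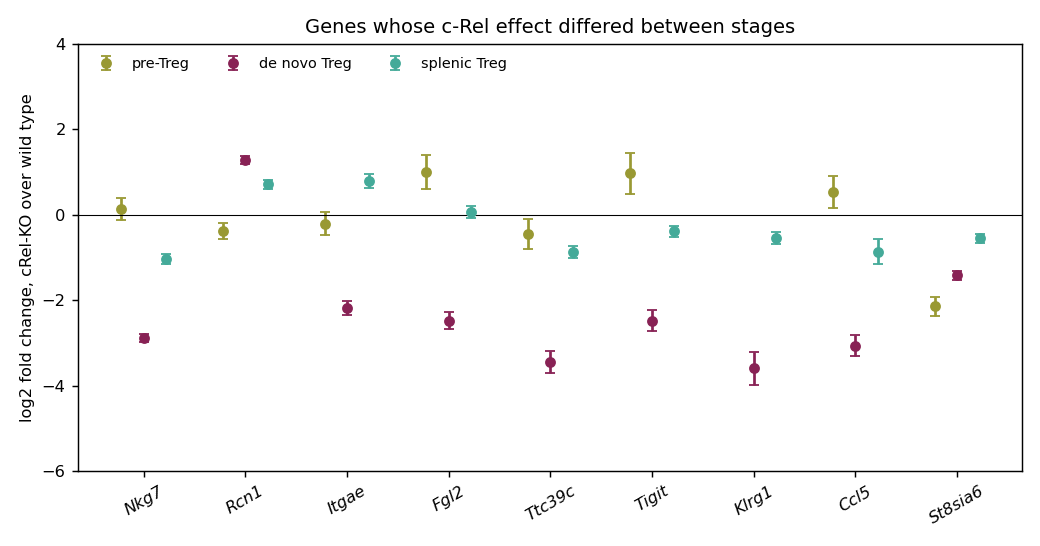
Log2 fold change of c-Rel knockout over wild type (points) with its SE (bars) in pre-Tregs, de novo Tregs and splenic Tregs for 9 genes whose effect differs between stages. Nkg7 stands at 0.13, −2.88 and −1.03; Klrg1 was not tested in pre-Tregs.

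In wild-type cells, Foxp3 rose from pre-Tregs to de novo Tregs (log2 fold change 3.63, SE 0.48, n = 2 per group, edgeR adjusted p = 0.000321), with Socs2 (4.55, SE 0.29), Gpr83 (3.92, SE 0.31), the kinase gene Pim1 (3.81, SE 0.24), Il2ra (2.49, SE 0.40) and Ctla4 (2.35, SE 0.18). The cells were sorted from Foxp3 reporter mice, so the sort itself may set the Foxp3 difference. Ikzf2 fell (−1.33, SE 0.23), as did the proliferation marker Mki67 (−1.36, SE 0.18) and Ccr9 (−2.31, SE 0.24). Rel was not called (0.02, SE 0.15, adjusted p = 0.93). Of 30 Treg signature genes 24 rose and 3 fell (26 and 3 over the list alone), of 20 IL-2 and STAT5 response genes 16 rose (16 over the list alone), and of 30 proliferation genes 21 fell (23 over the list alone). Of 13058 genes 2101 rose and 1914 fell. The total of 4015 became 1545 and 1775 without pre-Treg wild-type replicate 1 and 2, 6025 without pre-Treg knockout replicate 2, and 1690 and 1274 without de novo wild-type replicate 1 and 2. Stage and count table coincide, so any technical difference between the tables would be part of each of these values.

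From de novo to splenic Tregs in wild type, the chemokine receptor gene Cxcr3 (2.62, SE 0.37), Klrg1 (2.62, SE 0.31), the transcription factor gene Maf (2.48, SE 0.30) and S100a6 (2.12, SE 0.25) rose. Sox4 (−2.04, SE 0.24), Tnfaip3 (−1.57, SE 0.25), Ifi44 (−3.16, SE 0.41) and Rel itself (−0.99, SE 0.15, edgeR adjusted p = 0.00176) fell, with n = 2 per group. Foxp3 (−0.16, adjusted p = 0.882), Il2ra (−0.54, adjusted p = 0.47) and Ikzf2 (0.28, adjusted p = 0.536) were not called. Of 27 effector Treg genes 12 rose and 1 fell (18 and 1 over the list alone), of 28 interferon response genes 3 rose and 16 fell (4 and 20), and of 22 immature thymocyte genes 1 rose and 11 fell (1 and 15). Of 13058 genes 457 rose and 516 fell. The total of 973 became 257 and 377 without de novo wild-type replicate 1 and 2, 315 and 262 without splenic wild-type replicate 1 and 2, and 1527 and 2230 without pre-Treg knockout replicate 1 and 2. Tissue, stage and count table coincide in this comparison.

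Genes near Rel, on chromosome 11 at 23736847 to 23770970, did not pass the test for an excess of calls. Within 10 Mb, 6 of 69 tested genes were called in de novo Tregs (8.70% against 6.45% elsewhere; odds ratio 1.38, Fisher exact p = 0.455), among them Npm1. In splenic Tregs 0 of 75 were called, against 1.38% elsewhere (exact p = 0.629).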

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

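The tests of CD8 T and NK cell markers, of the totals of the libraries, of the fit without pre-Treg knockout replicate 2, of gene length and of thymic stroma markers were chosen after the result was seen.

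The genes below came up because their c-Rel effect differs between stages by the edgeR interaction test. Nkg7 (interaction adjusted p = 0.00596), Ttc39c (0.0136), Tigit (0.0152), Klrg1 (0.0171) and Ccl5 (0.0245) had lower log2 fold changes in de novo than in splenic Tregs, though the direct comparison of the 2 stages passed for Itgae alone. Fgl2 (0.0136) and Itgae (0.0111) were lower in de novo knockout Tregs but had positive log2 fold changes in the spleen, 0.06 and 0.79, neither called. Rcn1 (0.0102) was higher in both de novo and splenic knockout Tregs, with −0.38 in pre-Tregs. St8sia6 (0.0245) had its largest fold in pre-Tregs, −2.14. Mpo (0.0252) had 47 and 220 counts in wild-type and 0 in both knockout splenic libraries. Myeloid and dendritic markers lay below 0 for 16 of 19 in the same splenic comparison. Whether such cells account for the Mpo counts was not tested. None of the 10 kept its call in every fit that left out 1 library, since 0 genes are called without de novo knockout replicate 2.

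Effector Treg genes were lower in de novo knockout Tregs. A difference in library size is argued against: the largest total exceeds the smallest by a log2 ratio of 0.17, against a median log2 fold change of −0.87; at totals this close, thinning them decides nothing. CD8 T or NK cells in the wild-type sort, though the labels name enrichment for CD4 T cells before it, cannot be told apart from a change within the Tregs: 4 of the 10 tested markers had log2 fold changes above 0, none of them called, Klrb1c (1.23), Klrk1 (0.29), Prf1 (0.28) and Gzma (0.04), while Nkg7, Eomes and Ctsw were called lower and the markers summed to 1101 CPM in wild type and 649.7 CPM in the knockout. A smaller share of spleen-like mature Tregs in the knockout sort cannot be told apart either. Genes higher in the spleen, effector genes left out, had a median log2 fold change of −0.0749 (bootstrap SE 0.0282). This lay inside the range of 1000 random sets (−0.0877 to 0.0415) but near its low end, with 26 called lower and 21 higher. The set was chosen with the same de novo wild-type libraries that enter the fold tested. Noise in them pushes this median upward, so its place inside the range does not count against such a share. A direct effect of c-Rel on these genes stays open as well and was not tested here.

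In pre-Tregs edgeR and limma-voom called 0 genes, while DESeq2 called 88 with all 5 libraries. For edgeR, knockout replicate 2 may account for this by widening the spread, since 64 genes were called without it and 0 without any other single library; DESeq2 made its calls with that library included. Its log ratio to the other knockout libraries fell with gene length (Spearman −0.403 across 10562 genes), against −0.0392 between knockout replicates 1 and 3 and 0.0884 between the wild-type libraries. A technical difference in that library could thus be part of the cause for edgeR. A c-Rel effect that differs by stage stays open, as de novo and pre-Treg effects differed for 11 genes and splenic and pre-Treg effects for 28. The fit behind these counts had a common biological coefficient of variation of 0.189, against 0.284 in pre-Tregs alone. It may thus understate the pre-Treg spread. The count of 0 also depends on the model. With all 5 libraries edgeR called 71 genes in the shared fit and 14 without the count filter. It called 67 with a term for naming style and 77 with one for replicate number. Knockout replicate 2 is the only library of its naming style, and knockout replicate 3 the only pre-Treg library of its number. Each term fits the lone library exactly, so both counts rest on the other libraries.

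Gcg and Tnnt2, genes of other tissues, were lower in de novo knockout Tregs. For Tnnt2, reads running on from a neighbour may be the source: Lad1, which ends 3012 bases away on the same strand and is read at 579 CPM in wild type, had a log2 fold change of −4.30, beside −4.38 for Tnnt2. A fall of the whole region stays open too, since Tnni1, upstream of Lad1 on the same strand and out of reach of such reads, was called lower as well (−3.15, SE 0.57, adjusted p = 0.00699). For Gcg, 0 tested genes lay near enough to decide this, and no biological explanation was tested for either gene. RNA of thymic stroma in the wild-type libraries is argued against only in part. Gcg had 165 and 166 counts there, while 10 of 16 stroma markers had over 10 times fewer than Gcg or Tnnt2 in both libraries. Among these Krt5, Psmb11, Cxcl12 and Col3a1 were at 0, which argues against stroma rich in such markers. Aire, also a stroma marker, had 14 and 19 counts against 3 and 5 in the knockout, so RNA of stroma that expresses Aire stays open.

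For the genes called over all stages, 100 of 360 possible splits of the libraries within stages were drawn. In 1 of them, the real grouping, as many genes were called as the 111 reported. The highest of the others was 19, and 95 of the others had 0, so a chance arrangement of the libraries is argued against. No label states whether libraries of a group share an animal or preparation. If they do, the splits cannot tell genotype from that sharing. The tests on spleen-like Tregs, CD8 T and NK markers, library size and stroma markers were changed after their first results were seen. The reasons are the spread of the median, the lack of CD8 T and NK markers called higher, the similar totals that leave thinning without effect, and the expression of Epcam, a stroma marker called higher, by T cells.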

How the results depend on the processing

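The fit over all stages without the pre-Treg libraries, pre-Tregs with protein-coding genes only and the replicate number as a term across stages were chosen after the result was seen. RLE scaling and the stricter filter left every count of called genes within 1.5-fold. Without the count filter, 14 genes were called in pre-Tregs, 475 in splenic Tregs, 199 for the interaction and 163 in the overlap of de novo and splenic Tregs. DESeq2 called 88 in pre-Tregs, 526 in splenic Tregs, 327 over all stages, 504 for the interaction, 1583 for splenic versus de novo wild-type Tregs and 167 in the overlap; limma-voom called 191 over all stages. The replicate number as a block gave 77 in pre-Tregs, 361 in splenic Tregs, 35 over all stages, 4 for the interaction and 114 in the overlap. Libraries of the same number were not more alike than others (correlations −0.130, −0.0861, −0.0658 and −0.0838). In a group of 2 libraries the deviations from the mean mirror each other, so these values cannot decide whether the numbers mark pairs. The naming style as a block gave 67 in pre-Tregs, where knockout replicate 2 is the only library of its style. One fit sharing the spread over stages gave 71 in pre-Tregs, 100 in de novo Tregs, 60 in splenic Tregs and 14 in the overlap. It imposes the wider pre-Treg spread on the other stages and a narrower spread on pre-Tregs. Without the pre-Treg libraries 649 genes were called over all stages. Apart from these, the cause was not tested. Of the 34 list calls, 0 remained with an estimated correlation. Fry gave 7 calls, 6 of them among the 34 and all 6 in de novo Tregs. Leaving out 1 library gave 0 to 64 calls in pre-Tregs, 527 to 761 in de novo Tregs, 220 to 2508 in splenic Tregs, 44 to 217 over all stages, 0 to 296 for the interaction, 1274 to 6025 for de novo versus pre-Tregs and 257 to 2230 for splenic versus de novo Tregs. The call on genes near Rel did not change with windows of 5 or 20 Mb or with the replicate block, the alternatives run for it. Within 20 Mb, 15 of 145 genes were called in de novo Tregs (10.3% against 6.41% elsewhere, odds ratio 1.68, Fisher exact p = 0.0612). In splenic Tregs 2 of 151 were called (1.32% against 1.37%). Some list directions reversed when 1 library was left out, with camera adjusted p as follows. Erythroid and platelet markers in pre-Tregs ranged from 0.000103 to 0.671, reversing without wild-type replicate 1 (0.0103). Proliferation genes in de novo Tregs ranged from 8.05e-09 to 0.442, reversing without wild-type replicate 2 (0.442). In splenic Tregs without knockout replicate 1, ribosomal proteins (2.93e-07 to 0.822) reversed at 0.822 and oxidative phosphorylation (7.36e-11 to 0.744) at 0.744. Proliferation genes over all stages ranged from 0.000541 to 1.00, reversing without splenic knockout replicate 2. Of the named called genes, 59 of 82 in de novo Tregs, 30 of 38 in splenic Tregs, 20 of 28 over all stages, 0 of 10 for the interaction, 51 of 77 for de novo versus pre-Tregs and 24 of 53 for splenic versus de novo Tregs kept their calls without any 1 library; none reversed. Depth limits genes near the floor of 3 counts, at most 0.223 CPM.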

Other observations

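No test in this part was chosen after the result was seen. Several genes were called over all stages and not yet described: Nrp2, a semaphorin coreceptor gene (−1.59, SE 0.27), Fam129a (−1.46, SE 0.21) and Swap70, a guanine exchange factor of activated lymphocytes (−0.65, SE 0.08), fell in c-Rel knockout cells, while Nrgn (1.24, SE 0.17) and Pdzk1ip1 (1.33, SE 0.21) rose (edgeR, 13 libraries). In splenic knockout Tregs Naip5, an inflammasome sensor gene (1.86, SE 0.17), and Myo3b (1.76, SE 0.13) rose, and Pbk, a mitotic kinase gene (−1.63, SE 0.26), fell. From pre-Tregs to de novo Tregs in wild type the proapoptotic gene Bcl2l11 fell (−2.04, SE 0.17) and Socs3 rose (2.39, SE 0.15), and from de novo to splenic Tregs Fas (−1.06), Satb1 (−1.25) and Stat5a (−1.31) fell.

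Camera's direction and the sign of the median log2 fold change differ for a few lists: erythroid and platelet markers in pre-Tregs (median −0.39), early TCR response (0.01) and heat shock genes (−0.14) in splenic Tregs, and cytosolic ribosomal protein (0.00), resting (0.03), immature thymocyte (0.02) and heat shock genes (−0.04) over all stages. Among the pre-Treg libraries, knockout replicate 2 has the largest total (29866696 counts), the highest ribosomal protein share (1.07%) and the lowest mitochondrial share (0.388%).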
